A study of Mus musculus with 8 samples.

How the data were processed

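The material was mouse bone marrow taken after a stem cell transplant in animals carrying Vk12653, a transplantable mouse myeloma (a cancer of plasma cells). T cells and myeloid cells positive for CD64, the high-affinity IgG receptor, had been sorted, and the sorted cells went through droplet single-cell sequencing with a 10x Genomics 5' Next GEM kit, per the labels' protocols. The design has 2 factors, giving 4 groups: an isotype control antibody, an antibody against the receptor CSF-1R, lenalidomide (a drug that binds cereblon, the product of Crbn), and the antibody with lenalidomide, called the combination here. Lenalidomide was given at 50 mg/kg for 21 days and the antibody at 400 µg per mouse for 4 weeks, starting 7 days after the transplant, per the labels. Whether the group with lenalidomide alone received an isotype antibody is not given in the sources used here, so comparisons with that group, and departures from additivity, can include the presence of an antibody as such. The libraries with lenalidomide came from mice labelled CRBN and the others from mice labelled WT, so drug and genotype change together and cannot be told apart by any comparison across them. Each group has 1 gene expression library and 1 library named for surface protein, 8 samples in total.

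The deposited values were counts of unique molecular identifiers (UMIs) per feature and barcode, made by the authors with Cell Ranger 8.0.0, per the file headers, on the mouse genome build mm10, per the submitters' processing notes. The annotation version, the rule that called barcodes as cells and any earlier filter on cells are not given in the sources used here. The deposited feature tables listed 32285 genes and 5 antibody tags named as hashtags (HT01 to HT05) with the type of each feature as a word, and no surface protein, so the planned surface protein values could not be computed. Gene symbols were those of the feature tables, and 32158 of the gene IDs were found in a gene name table while 127 were not. Each library was matched to its sample by the number that its name and the sample's description share. What a hashtag marks (an animal or another unit) is not given in the sources used here, so hashtags were not treated as replicates, and ranges over hashtags are descriptions.

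Barcodes with at least 500 UMIs of gene expression, at least 300 genes and at most 10% mitochondrial UMIs were kept. Scrublet (in scanpy 1.11.5) was run per library with an expected rate of 0.8% per 1000 barcodes, and barcodes over its automatic threshold were left out. A barcode carried a hashtag when its count passed a threshold set per library and hashtag by k-means with a low and a high centre on log10 counts. The isotype control library had 14887 barcodes, of which 14523 were kept, 2176 (15.0%) were called doublets and 12347 were analysed. The matching numbers were 17842, 17523, 594 (3.39%) and 16929 with anti-CSF-1R, 19042, 18510, 271 (1.46%) and 18239 with lenalidomide, and 23623, 23406, 697 (2.98%) and 22709 with the combination. Several hashtags were carried by 22.6%, 27.2%, 24.6% and 19.9% of all barcodes in that order, and still by 15.2%, 25.5%, 24.4% and 18.0% of those analysed. The caller thus removed a far larger share of the isotype control library than of the others, and doublets remain in all 4.

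Counts were scaled per cell and log-transformed, 2000 highly variable genes were chosen without antigen receptor, mitochondrial, ribosomal, haemoglobin and sex-linked genes, and 30 principal components were computed. Cells were joined to 15 neighbours (scikit-learn 1.9.0) and clustered over all libraries together with the Leiden method at resolution 1 (leidenalg 0.10.2, igraph 0.11.9), with no correction between libraries. Clusters were named "X-like" from fixed marker lists. Of the 36 clusters, 8 in which at least 40% of barcodes carried several hashtags were set apart as mixed, a threshold chosen after the data were seen, and 6 stayed unnamed. The mixed clusters held 8.48% of the isotype control, 18.9% of the anti-CSF-1R, 17.2% of the lenalidomide and 12.4% of the combination library. The unnamed ones held 2.17%, 0.61%, 1.29% and 2.40%. T-like clusters not named CD8, CD4 or regulatory are called other T. They include cycling, interferon-induced and NK receptor-bearing clusters in which a Cd8a UMI was found in 55.3% to 62.5% of cells, so the CD8 T-like share leaves out part of the CD8 T cells.

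For each class and library the UMIs were summed over cells and expressed as CPM, counts scaled by the class total to a common size. Each CPM has an exact Poisson 95% interval and each share of cells an exact Clopper-Pearson 95% interval. These intervals cover counting error only, not the difference between animals or between library preparations. The CPM intervals treat each UMI as independent, so they leave out the variation between cells of a class too. Folds are log2 of (CPM + 10) over (CPM + 10), which understates the change of genes with low counts. With 1 library per group no test between groups is possible, and no p-value, standard error or count of changed genes was computed. A comparison below is one of libraries, and "higher" or "lower" describes these libraries. Comparisons of anti-CSF-1R and of lenalidomide with the isotype control share that library, so any peculiarity of it enters both with the same sign.

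The cell filters, markers, gene lists, the rule for named genes, the thinning and the alternative settings, other than those said below to be added, were fixed before the data were examined. There were 17 gene lists: T exhaustion, T effector, T memory and naive, lenalidomide target and IL-2 axis, type I interferon response, interferon gamma response, MHC class II, cell cycle, resident macrophage, alternative activation, inflammatory myeloid, non-classical monocyte, myeloma-supporting factors, dissociation stress and, as markers of other cell types, neutrophil granule, erythroid, and plasma cell and myeloma. A list's value is the median log2 fold of members with at least 10 CPM in either library, given where at least 3 members were measured. With it go the number of members at least 1.5 times higher or lower and the median's percentile among 10000 random lists of the same size matched on mean expression, which describes these libraries only. The interval of a list median comes from redrawing each count from a Poisson distribution.

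The genes named in the text followed this rule. In the CD8 T-like, CD4 T-like, classical monocyte-like and macrophage-like classes with at least 100 cells in both libraries, the 3 genes most above and the 3 most below in each of 4 comparisons were taken. They needed at least 50 CPM and 30 UMIs in the higher library, counting intervals that did not overlap, and at least 5% of the gene's highest CPM in any other class of that library. Receptor segments, mitochondrial, ribosomal, haemoglobin and sex-linked genes and unnamed gene models were left out. Crbn, Csf1r and up to 4 members per list furthest from 0 were also named. The combination held 79 macrophage-like cells, so its comparisons in that class were left out. Where a gene is named in a further library or class for its level there, that was chosen after its values were seen.

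Shares of cells with a UMI of a gene were also computed after thinning each cell to 1000 UMIs, with shallower cells left out. The alternative settings fixed in advance were stricter cells (at least 1000 UMIs and 600 genes, at most 5% mitochondrial), doublets kept, Leiden resolution 0.5, genes centred per library before the components, TMM scaling (edgeR 4.0.16 in R 4.3.3), the mean over cells, a pseudocount of 1 CPM and no minimum CPM for list members. Clustering only barcodes with 1 hashtag, leaving out each isotype hashtag and hashtags 2 and 3 together, leaving out of every library the hashtags in which 1 Trbv segment took over 20% of CD8 T-like cells with 1 segment (a limit chosen after the shares were seen), weighting hashtags equally, taking non-classical cells as a share of monocyte-like cells only and calling them by at least 2 of 5 markers (Treml4, Ace, Cd300e, Eno3 and Spn) in thinned cells were added after the data were seen. Equal hashtag weights were applied to list medians and their departures only, not to shares or single genes. The fold and list steps were tested on simulated counts for anti-CSF-1R against isotype control, with 100 genes changed by 2-fold and 100 by 4-fold. Counting intervals lay apart in the right direction for 100.0% of both sets, in the CD8 T-like class (3346 genes) and in the classical monocyte-like class (3372 genes). They lay apart for 2.0% and 1.1% of the unchanged genes. The simulated counts were Poisson draws around a mean shared by both libraries, with no variation between cells, hashtags or libraries. That is the model of the intervals, so these percentages check the steps and do not give the error in the real libraries. Other software was python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.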

Results

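Single-cell transcriptomes were collected from sorted T cells and CD64-positive myeloid cells of myeloma-bearing mice after transplant, in 4 groups with 1 gene expression library each. The total depth was 90934658 UMIs in the isotype control library, 112918163 with anti-CSF-1R, 98343087 with lenalidomide and 132271908 with the combination. Median UMIs per barcode were 4873, 4938, 3994 and 4596 in that order. T-like classes made up 60.1%, 55.8%, 50.5% and 57.7% of the analysed barcodes and myeloid-like classes 27.5%, 23.4%, 29.3% and 26.6%, a balance that the sort sets. No group has a second library, so every interval below covers counting error only and every difference is one between libraries.

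Crbn and Csf1r, the genes behind the genotype and the antibody target, were read first. Crbn stood at 74.9 CPM (70.8 to 79.2) in CD8 T-like cells of the isotype control, 59.2 (55.8 to 62.8) with anti-CSF-1R, 60.5 (56.6 to 64.6) with lenalidomide and 64.1 (60.6 to 67.7) with the combination. In classical monocyte-like cells Crbn was at 26.2, 25, 27.1 and 20.6 CPM. The labels do not say which form of CRBN the mice labelled CRBN carry, so counts of the mouse gene do not check the genotype. Csf1r, the receptor that monocytes and macrophages need for survival and maturation, was highest in non-classical monocyte-like cells, at 823 CPM (775 to 872) in the isotype control, 936 (863 to 1014) with anti-CSF-1R, 674 (644 to 705) with lenalidomide and 923 (778 to 1087) with the combination. It stood at 319 (308 to 331), 262 (254 to 271), 237 (224 to 250) and 263 (256 to 270) CPM in classical monocyte-like cells and at 0.79 CPM or less in CD8 T-like cells. An antibody against the protein need not alter the transcript, so Csf1r counts do not check the treatment either.

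The first comparison asked what the anti-CSF-1R antibody did in wild-type mice. Non-classical monocyte-like cells, the patrolling monocytes that depend on CSF-1R signalling, formed 12.9% (11.8 to 14.1) of myeloid-like cells in the isotype control and 5.6% (4.90 to 6.36) with anti-CSF-1R, a log2 ratio of −1.20 (−1.41 to −0.96), and −0.60 when cells were called by markers after thinning. Across hashtags the share ran from 9.01% to 18.7% in the isotype control and from 3.37% to 8.20% with the antibody, so the ranges did not overlap. A mixed cluster with non-classical monocyte and T cell genes, kept out of this share, held 191 barcodes of the isotype control, 216 of the anti-CSF-1R, 889 of the lenalidomide and 45 of the combination library. Classical monocyte-like cells, their circulating precursors, made up 40.8% (39.2 to 42.5) and 50.1% (48.6 to 51.7). Their hashtag ranges overlapped, at 38.3% to 51.6% in the isotype control and 30.7% to 60.9% with the antibody. Macrophage-like cells were scarce, at 4.09% (139 cells) and 2.62% (104 cells), with overlapping hashtag ranges of 2.85% to 4.78% and 1.23% to 4.98%. A mixed cluster with macrophage and T cell genes, kept out of this share, held 425 and 396 barcodes. Among T-like cells, regulatory T-like cells, which restrain immune responses, formed 10.2% (9.49 to 10.9) in the isotype control and 6.34% (5.86 to 6.85) with the antibody, a log2 ratio of −0.68 (−0.83 to −0.53). By hashtag their share ran from 6.99% to 10.6% and from 4.52% to 5.65%. Several hashtags were carried by 26.9% of the barcodes in this cluster, which the hashtag ranges leave out and the pooled shares include. The CD8 T-like share was 51.1% and 49.6%, the CD4 T-like share 11.7% and 12.3% and that of other T cells, which hold CD8 cells as well, 27% and 31.7%.

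**Figure D1:**
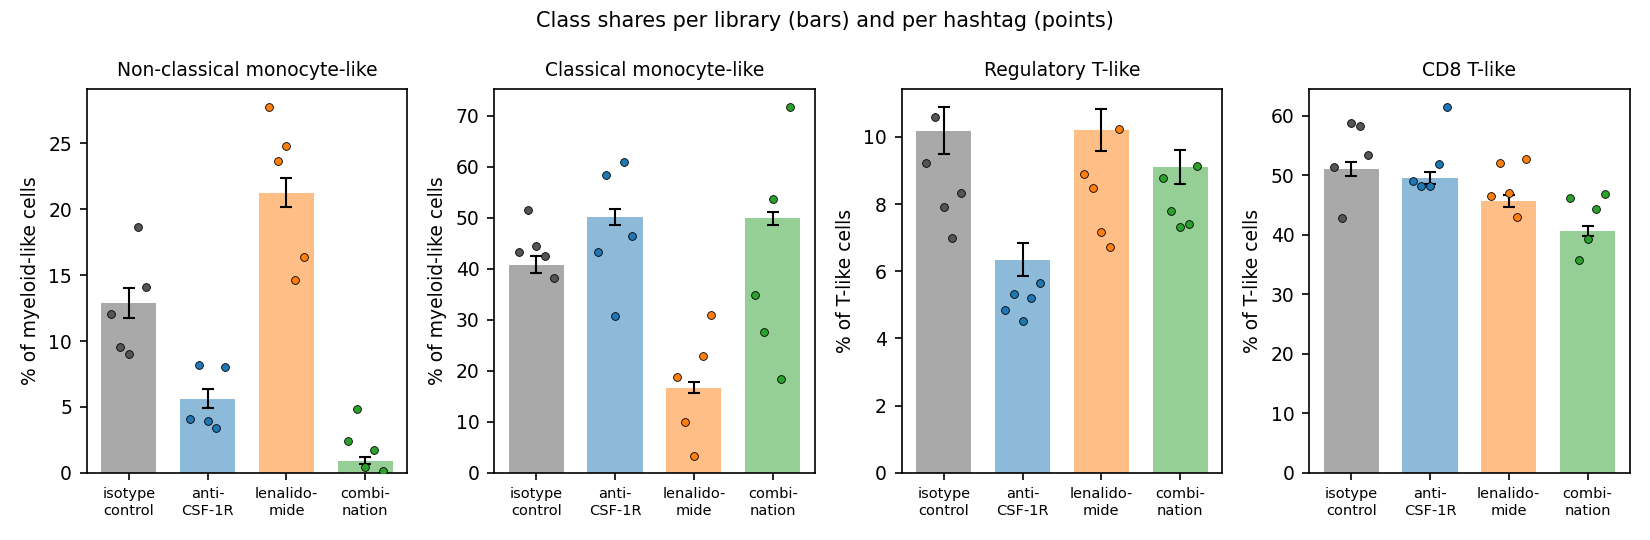
Shares of 2 myeloid-like classes (percent of myeloid-like cells) and 2 T-like classes (percent of T-like cells) in each library, with bars for the library, error bars for exact binomial 95% intervals (counting error only) and points for single hashtags, which leave out barcodes with several hashtags. The non-classical monocyte-like share ran from 0.89% with the combination to 21.2% with lenalidomide.

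CD8 T-like cells of the anti-CSF-1R library held lower levels of the T exhaustion genes than those of the isotype control. The list had a median log2 fold of −0.77 (−0.83 to −0.70), with 7 of 12 members at least 1.5 times lower, the bound for all member counts below, 0 higher, and a percentile of 0 among random lists. Pdcd1, which encodes the inhibitory receptor PD-1, stood at 132 CPM (127 to 138) in the isotype control and 53.4 (50.2 to 56.8) with the antibody. Other inhibitory receptors were lower too, with Lag3 at 65.2 and 27.4 CPM, Havcr2 (TIM-3) at 46.3 and 21.6 and Cd244a at 41.1 and 10.7. The T effector list had a median of −0.38 (−0.43 to −0.33), with 4 of 16 members lower and 0 higher. Gzma, a cytotoxic granule protease, was at 485 CPM (475 to 496) and 158 (152 to 164), and the chemokine Ccl5 at 19181 and 9451, while Tnf, at 38.0 and 43.4, went the other way. The memory and naive list was at 0.22 (0.16 to 0.24), led by Il7r (256 and 318 CPM), the IL-7 receptor of long-lived T cells, and Satb1 (212 and 278), with Id3 slightly lower (75.9 and 67.0). Xcl1, a chemokine that attracts dendritic cells, was the gene most above, at 192 CPM in the isotype control and 360 with the antibody, followed by Polr2l (39.3 and 75.1) and Brd1 (46.4 and 81.3).

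A Pdcd1 UMI was found in 24% of CD8 T-like cells in the isotype control and 11.5% with anti-CSF-1R, and after thinning to 1000 UMIs in 12.9% and 5.30% (184 and 156 shallower cells left out). In neutrophil-like cells, which lack PD-1, the shares were 0.55% and 1.48%, at median depths of 10736 and 9015 UMIs against 3719 and 3508 in CD8 T-like cells. The isotype control library varied between its hashtags. A CD8 T-like cluster led by Gzma, Ccl4 and Pdcd1 held 17.1% of that library's CD8 T-like cells and 5.18% with the antibody, while by hashtag it held 3.23%, 30.4%, 32.2%, 3.79% and 8.62% in the isotype control. In hashtag 3 there, Trbv19, a T-cell receptor beta segment, took 46.9% of CD8 T-like cells with 1 segment, and the next segment 7.50%. In hashtag 2 Trbv13-1 took 31.5%. Leaving out hashtag 3 gave an exhaustion median of −0.60, leaving out hashtag 2 gave −0.66, and leaving out both gave −0.40. Leaving out a hashtag removed only barcodes that carried it alone. Barcodes with several hashtags or none stayed in, so cells of these hashtags can remain. Applied to every library, leaving out hashtags whose leading segment took over 20% (also hashtag 5 with anti-CSF-1R, at 20.5%, and hashtags 4 and 5 with lenalidomide, at 20.8% and 23.9%) gave −0.28. The 20% was chosen after these shares were seen, and leaves in hashtag 5 of the combination, at 19.4%.

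**Figure D2:**
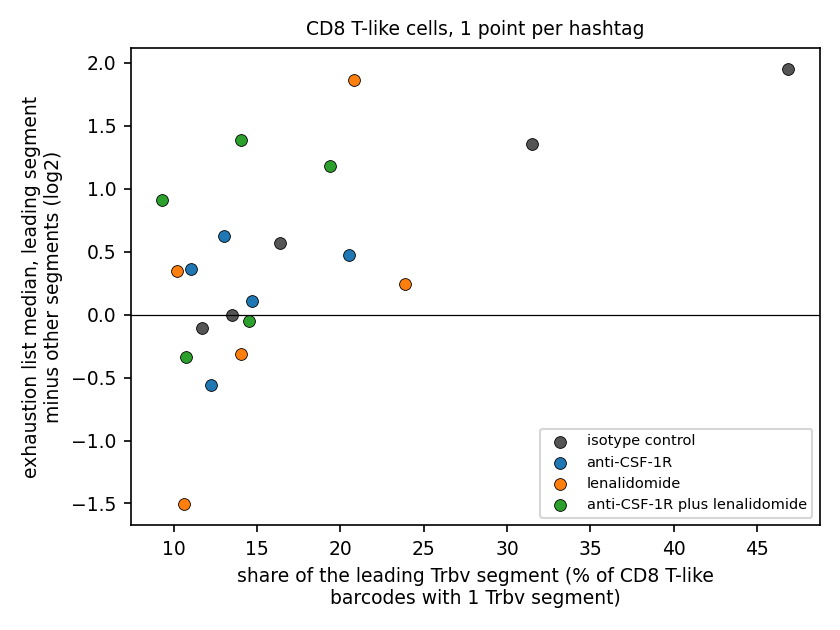
Each point is 1 hashtag of 1 library, with the share of its leading Trbv segment among CD8 T-like barcodes with 1 segment on the x axis (percent) and the exhaustion list median in cells with that segment minus that in cells with other segments on the y axis (log2). The point furthest right is hashtag 3 of the isotype control, at 46.9% and 1.95.

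In classical monocyte-like cells, proliferation genes and granule genes were higher with anti-CSF-1R than in the isotype control. The cell cycle list had a median of 0.82 (0.75 to 0.91), with 9 of 12 members at least 1.5 times higher and 0 lower. Among them were Stmn1, a regulator of microtubules in dividing cells, at 55.2 CPM in the isotype control and 137 with the antibody, and Pclaf, a DNA replication factor, at 24.1 and 69.6. A mixed cluster of cycling monocytes, kept out of the class, held 31 barcodes of the isotype control, 149 of the anti-CSF-1R, 67 of the lenalidomide and 190 of the combination library, of which 6.50%, 41.6%, 67.2% and 40.5% carried several hashtags. Prtn3, a granule protease of immature myeloid cells, was at 116 and 294 CPM. The neutrophil granule list was at 2.21 (2.08 to 2.33), with 4 of 5 members higher, and 0.10 with no minimum CPM. Its leading members were the calprotectin genes S100a8, at 124 CPM (117 to 131) and 1736 (1714 to 1758), and S100a9, at 13.6 and 220. S100a8 ran from 81.5 to 146 CPM across isotype control hashtags and from 719 to 2812 across those of the antibody. The same gene stood at 83.5 and 81.7 CPM in CD4 T-like cells, which are not known to make it, and at 143571 and 145050 in neutrophil-like cells. Lower with the antibody were Hpgd, which breaks down prostaglandins, at 120 and 27.1 CPM, Apoe, a lipid carrier of maturing macrophages, at 424 and 158, and Cx3cr1, a receptor of the non-classical lineage, at 204 and 82.1.

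MHC class II genes, which present antigen to CD4 T cells, had a median of 0.67 (0.58 to 0.76) in classical monocyte-like cells with anti-CSF-1R, with 3 of 6 members higher and 0 lower. H2-Aa was at 19.7 and 53.5 CPM, H2-Eb1 at 3.77 and 20.1 and H2-DMa at 185 and 176. A Cd74 UMI was found in 48.1% of these cells in the isotype control and in fewer, 42.5%, with the antibody, and after thinning in 18.5% and 20%. The list median depended on where clusters were drawn, since it was 0.03 at Leiden resolution 0.5, where 86.8% of dendritic-like cells fell into this class. The type I interferon list was at −0.20 (−0.24 to −0.13), with 1 of 14 members lower, led by the antiviral genes Ifit3 (47.2 and 27.4 CPM) and Rsad2 (20.9 and 11.4). A mixed cluster of monocytes high in Ifit3 and Rsad2, kept out of the class, held 103 barcodes of the isotype control, 312 of the anti-CSF-1R, 219 of the lenalidomide and 310 of the combination library, beside 1386, 1988, 893 and 3016 classical monocyte-like cells, so interferon values of this class leave out uneven parts of the monocytes. The interferon gamma list was at 0.20 (0.15 to 0.32), with 1 of 11 members higher, the GTPase gene Gbp2 (37.2 and 66.0 CPM). The inflammatory myeloid list was also at 0.20, with 1 of 7 members higher, and at −0.01 with no minimum CPM, and dissociation stress was at 0.04. Resident macrophage genes were at −0.28 (0.03 with no minimum), led by Trf, the iron carrier transferrin (160 and 86.8 CPM), and alternative activation at −0.14. Myeloma-supporting factors were at −0.32 with 0 of 4 members past 1.5 times in either direction, among them Tnfsf13b, the plasma cell survival factor BAFF, at 12 and 6.24 CPM. The non-classical monocyte list was at −0.00 over 4 members.

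**Figure D3:**
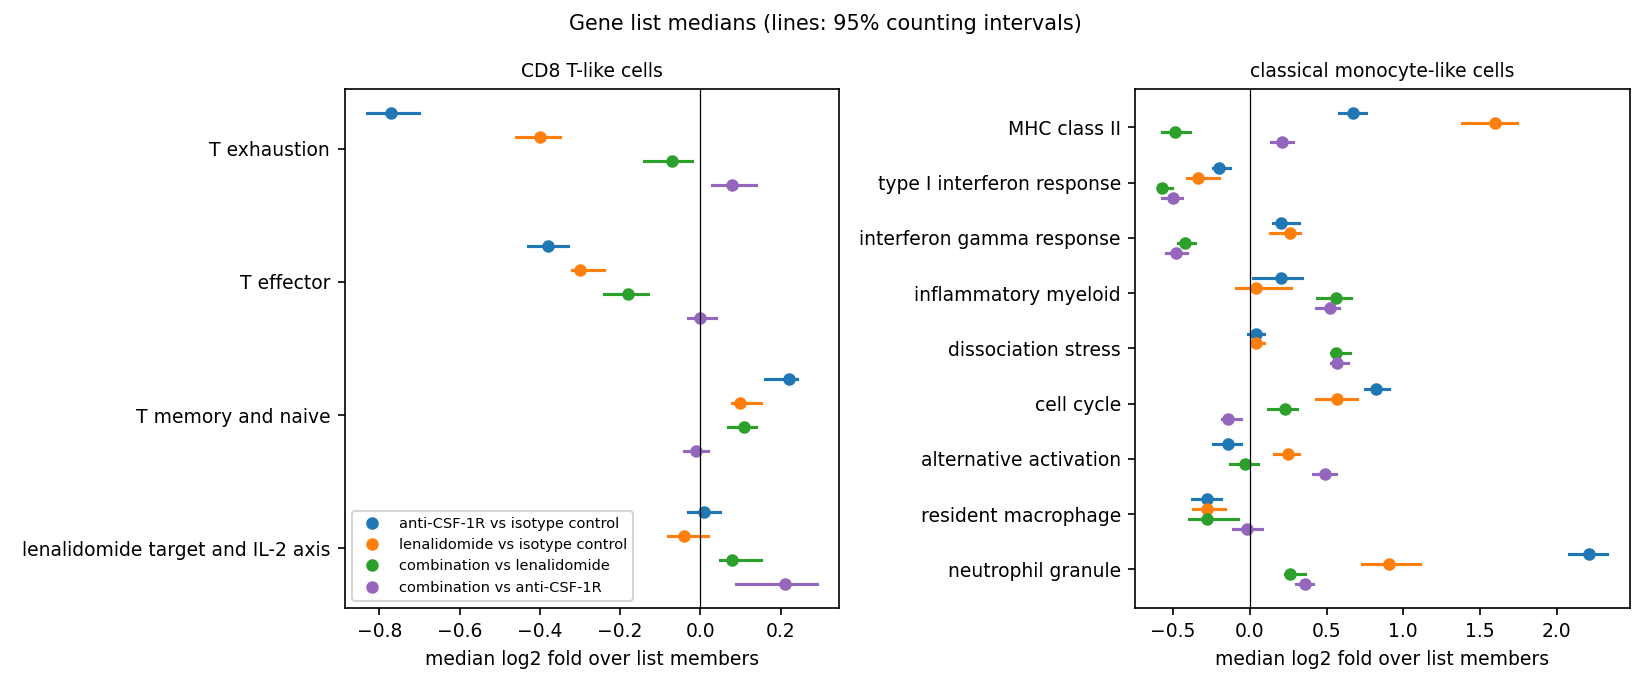
Median log2 folds of gene lists (x axis) in CD8 T-like cells (left) and classical monocyte-like cells (right) for 4 comparisons, with lines for 95% counting intervals. T exhaustion was lowest with anti-CSF-1R against isotype control, at −0.77, and MHC class II highest with lenalidomide against isotype control, at 1.60.

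CD4 T-like cells differed less between the anti-CSF-1R and isotype control libraries. Their effector list was at −0.00 and their exhaustion list at −0.08, and the memory list stood at −0.13. Spp1, the cytokine osteopontin, was at 50.4 CPM with the antibody (UMIs in 10 of 1160 cells) and 21.7 in the isotype control (9 of 870 cells). In the isotype control 48.2% of its UMIs came from 1 barcode. Cul3, part of a ubiquitin ligase, was at 154 and 87.4. Cd8a was at 50.4 and 25.2 CPM, a direction that turned at Leiden resolution 0.5 (−0.41) and with 1-hashtag barcodes only (−0.47). Ccnb1ip1 was lower (28.2 and 83.1). The chemokine Ccl3 was at 50.0 and 132 CPM, with 66.3% of its isotype control UMIs in 1 barcode. Without the top barcode of each library it stood at 40.9 and 44.7, and its fold of −1.25 was −0.25 with stricter cells. MHC class II genes, which T cells of mice do not make in quantity, were at −0.75 in this class, with H2-Aa at 15.8 and 41.2 CPM. In macrophage-like cells, with median UMIs of 761 and 757, MHC class II genes were at −0.84, with 5 of 7 members lower and Cd74, the invariant chain, at 2236 CPM with the antibody and 5002 in the isotype control. Irf7, an interferon regulator, was at 126 and 402 CPM there and Ccni at 87.5 and 250, while Cdk8 was at 17955 and 3810, with 33.4% of its UMIs with the antibody in 1 barcode and a fold of 1.61 in place of 2.23 with 1-hashtag barcodes only. The resident macrophage list was at −0.17 and the inflammatory list at 1.22 in that class. Slpi had 2 UMIs with the antibody and 41 in the isotype control, of which 73.2% came from 1 barcode, and stood at 9.8 and 84.5 CPM without the top barcode of each. Malat1 and Ccl5 rested largely on 1 barcode, which gave 57.6% and 72.6% of their UMIs with the antibody. The Malat1 fold of 1.76 was −0.03 with 1-hashtag barcodes only, and the Ccl5 fold of 1.35 was −0.00 as a mean over cells.

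Nkain2, which encodes a membrane protein that interacts with the sodium pump, was lower with anti-CSF-1R in every class with at least 100 cells. In CD8 T-like cells it was at 176 CPM (170 to 183) in the isotype control and 16.5 (14.7 to 18.4) with the antibody, in CD4 T-like cells at 180 and 21.1, and in classical monocyte-like cells at 156 and 13.6, a fold of −2.81 that was −3.42 with a pseudocount of 1 CPM.

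The second comparison set lenalidomide in CRBN mice against the isotype control in WT mice, so it holds the drug and the genotype together. Non-classical monocyte-like cells made up 21.2% (20.2 to 22.4) of myeloid-like cells with lenalidomide against 12.9% in the isotype control, a log2 ratio of 0.72 (0.58 to 0.87). The hashtag ranges overlapped, at 14.6% to 27.8% and 9.01% to 18.7%, and the ratio was 0.25 when cells were called by markers after thinning, with overlapping intervals of 7.36% to 8.86% and 5.96% to 7.71%. Classical monocyte-like cells made up 16.7% (15.7 to 17.7) against 40.8%, a log2 ratio of −1.29, which was −0.54 at Leiden resolution 0.5. By hashtag the classical share ran from 3.22% to 31% with lenalidomide and from 38.3% to 51.6% in the isotype control. Neutrophil-like cells were at 28.5% and 21.6%, granulocyte-monocyte progenitor-like cells at 9.04% and 4.89% and macrophage-like cells at 2.36% and 4.09%. The progenitor-like cluster was led by Elane and Mpo but held S100a8 at 135413 CPM, beside 132986 in a cycling neutrophil-like cluster. At Leiden resolution 0.5, 98.0% of it fell into the neutrophil-like class, so its share need not be one of granulocyte-monocyte progenitors. The regulatory T-like share was 10.2% in both libraries, with a log2 ratio of 0.00 (−0.12 to 0.13). CD8 T-like cells were at 45.7% and 51.1% and CD4 T-like cells at 13.9% and 11.7%.

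Antigen presentation genes stood far higher in classical monocyte-like cells with lenalidomide. The MHC class II list had a median of 1.60 (1.38 to 1.74), with 5 of 7 members at least 1.5 times higher and 0 lower. Cd74 was at 1285 CPM (1254 to 1315) against 379 (367 to 391), H2-Aa at 108 against 19.7 and H2-Ab1 at 62.5 against 10.5, while H2-DMa was at 181 against 185. A Cd74 UMI was found in 59.5% of these cells against 48.1%, and after thinning in 35.4% against 18.5%. In neutrophil-like cells, taken as a background, a Cd74 UMI was found in 9.34% against 5.19%, and after thinning in 2.24% against 0.97%. The granule genes were higher as well, with S100a8 at 2014 CPM (1976 to 2052), S100a9 at 181 and a list median of 0.91, with 6 of 7 members higher. That median moved with the processing, to 1.90 with centred genes, 1.69 with a pseudocount of 1 CPM and 2.20 with hashtags weighted equally. The cell cycle list was at 0.57 (0.43 to 0.70) with 4 of 9 members higher, and Stmn1 was at 99.0 CPM against 55.2. Also above were Ier3, an early response gene, at 56.6 CPM against 15.8 and AW112010, an interferon-induced transcript, at 231 against 86.7. Lower were Cx3cr1 at 94.7 against 204, Ckb, a creatine kinase, at 21.3 against 57.3 and Padi4, an enzyme of neutrophil extracellular traps, at 49.7 against 107. The interferon gamma list was at 0.26 (1 of 12 members higher), the inflammatory list at 0.04, dissociation stress at 0.04 (−0.02 with hashtags weighted equally), the non-classical list at −0.17 and myeloma-supporting factors at −0.10, with Hgf at 14.9 against 20.9 CPM. The type I interferon list was at −0.34 with 2 of 14 members lower, and 0.12 at Leiden resolution 0.5. The alternative activation list, at 0.25, was −0.01 with no minimum CPM. The resident macrophage list, at −0.28, turned to 0.41 at Leiden resolution 0.5, 0.29 with hashtags weighted equally and 0.01 with no minimum CPM.

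In CD8 T-like cells lenalidomide went with lower exhaustion and effector genes. The exhaustion median was −0.40 (−0.46 to −0.35), with 2 of 12 members at least 1.5 times lower, Cd244a (15.7 against 41.1 CPM) and Havcr2 (24.1 against 46.3), and 0 higher. Pdcd1 was at 88.4 CPM (83.7 to 93.4) against 132. The effector median was −0.30 (−0.32 to −0.24), with Gzma at 234 CPM against 485 and Prf1, the pore-forming perforin, at 91.4 against 144, but Tnf higher at 51.3 against 38.0. The memory and naive list was at 0.10 (0.08 to 0.15). Il7r was at 434 CPM (423 to 445) against 256 and Ccr2, a homing receptor for inflamed tissue, at 113 (107 to 118) against 64.1, the only members of the top 3 that did not rest on 1 barcode. The third, the eosinophil granule gene Prg2, was at 153 against 0.24 CPM, with 87.1% of its 2260 UMIs in 1 barcode and a fold of 0.04 with stricter cells. Lower were Cd7, a surface receptor of T cells, at 227 against 466 and Cmss1 at 814 against 1580. The list of lenalidomide targets and the IL-2 axis was at −0.04, with Ikzf3, which encodes the drug's known degradation target Aiolos, at 409 against 397 CPM. Degradation acts on the protein, so these transcript counts do not check the action of the drug. The type I interferon list was at −0.12 in CD8 T-like cells. The isotype control library is the reference here too, and without its hashtags 2 and 3 the exhaustion median was −0.14, while the effector and memory medians turned to 0.01 and −0.01. That setting thins 1 side only, and with hashtags over 20% left out of both libraries the medians were −0.37, −0.32 and 0.08.

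CD4 T-like cells with lenalidomide had lower effector genes, with a list median of −0.55 (−0.64 to −0.42) and 6 of 14 members lower. Gzma was at 3.46 CPM against 30.7 and Ccl4 at 216 (199 to 234) against 545 (517 to 574), although 55.3% of the isotype control's Ccl4 UMIs came from 1 barcode and the fold of −1.30 ran from −0.35 with stricter cells to −2.46 with 1-hashtag barcodes only. The exhaustion list was at −0.45, with Tigit, an inhibitory receptor, at 73.4 against 132 CPM. Higher were the interferon-induced membrane genes Ifitm1, at 93.2 CPM (82.4 to 105) against 6.99 (4.14 to 11.1), a fold of 2.60 that was 3.56 with a pseudocount of 1 CPM, and Ifitm2, at 269 (251 to 289) against 45.4 (37.6 to 54.5), and Tmem176b, at 288 against 65.6, a channel gene of some helper T cells that was also among the leading genes of dendritic-like cells, at 760 against 480 CPM there. The cytokine receptor gene Il31ra (292 against 638 CPM) and the chemokine Ccl1 (21.8 against 54.8) had 45.0% and 78.0% of the isotype control UMIs in 1 barcode. Without the top barcode of each library they stood at 265 against 355 and at 11.8 against 12.1 CPM. The Il31ra fold of −1.10 was −0.40 as a mean over cells, and the Ccl1 fold of −1.02 lay between −2.95 and −2.64 with doublets kept, Leiden resolution 0.5 and centred genes. Il31ra was also among the leading genes of an unnamed cluster of shallow barcodes (median 1338 UMIs). The memory list was at −0.02, dissociation stress at 0.39 and the erythroid list at 1.42. In macrophage-like cells (126 against 139) MHC class II genes were at 0.73, with 5 of 7 members higher and 1 lower, and Cd74 was at 9427 against 5002 CPM. Cxcl9, an interferon-induced chemokine, was at 313 against 75.9 CPM, Ifitm2 at 327 against 75.9 and Pf4, a platelet chemokine, at 569 against 152. Arhgdib (114 against 342 CPM) and Wfdc17 (761 against 1609) were lower. Slpi was at 99.6 against 311 CPM, but at 84.1 against 84.5 without the top barcode of each library. The Wfdc17 fold was −0.47 in place of −1.07 as a mean over cells. The Cxcl9 fold of 1.91 was 0.86 with 1-hashtag barcodes only and 2.90 with stricter cells, and the Pf4 fold of 1.84 was 1.24 with stricter cells. With stricter cells the Ifitm2 fold there was 0.73 in place of 1.97, and the Arhgdib fold −0.45 in place of −1.51.

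The third comparison added the antibody to lenalidomide, with the CRBN genotype on both sides. Whether the group with lenalidomide alone received an isotype antibody is not given in the sources used here. Non-classical monocyte-like cells were nearly lost, with 54 of 6035 myeloid-like cells (0.89%, 0.67 to 1.17) in the combination against 1135 of 5344 (21.2%) with lenalidomide, a log2 ratio of −4.57 (−5.01 to −4.21), and −2.78 when cells were called by markers after thinning. The hashtag ranges were 0.15% to 4.83% and 14.6% to 27.8%. Classical monocyte-like cells were at 50.0% against 16.7%, with a log2 ratio of 1.58 that was 0.84 at Leiden resolution 0.5, and by hashtag from 18.3% to 71.7% in the combination. Macrophage-like cells were at 1.31% (79 cells) against 2.36%. Csf1r in classical monocyte-like cells was at 263 CPM against 237, a direction that turned at Leiden resolution 0.5 (−0.07). Regulatory T-like cells were at 9.09% (8.60 to 9.60) against 10.2%, CD8 T-like cells at 40.7% against 45.7%, CD4 T-like cells at 16.6% against 13.9% and other T cells at 33.7% against 30.2%.

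Classical monocyte-like cells of the combination held higher early response and inflammatory genes and lower interferon genes than those with lenalidomide alone. The inflammatory myeloid list had a median of 0.56 (0.44 to 0.66), with 4 of 8 members at least 1.5 times higher and 0 lower, but 0.08 with no minimum CPM. Cxcl2, a chemokine that draws neutrophils, was at 99.3 CPM (95 to 104) against 26.3 (22.2 to 31) and Ccl3 at 139 against 74.3, while Tnf was at 13.8 against 18.9. The dissociation stress list moved with it, also at 0.56 (0.53 to 0.65) with 4 of 8 members higher, including the transcription factor gene Atf3, at 433 CPM (423 to 442) against 140 (131 to 151), and the phosphatase gene Dusp1, at 846 against 313. Fosb, another immediate early factor, was at 128 against 35.8. The type I interferon list was at −0.57 (−0.60 to −0.51), with 6 of 12 members lower and 0 higher, among them Irf7 at 174 CPM (168 to 179) against 312 (297 to 327) and Rtp4 at 56.4 against 98.8. The interferon-induced DNA sensors Ifi205 (27.6 against 76.0 CPM) and Ifi213 (45.1 against 103) were lower too, and the interferon gamma list was at −0.42, with Gbp2 at 32.1 against 56.2. MHC class II genes were at −0.49 (−0.57 to −0.39), with Cd74 at 731 against 1285, and at −1.17 at Leiden resolution 0.5. The cell cycle list was at 0.23, the neutrophil granule list at 0.26 (1.11 at Leiden resolution 0.5) and the resident macrophage list at −0.28. Alternative activation was at −0.03, the non-classical list at 0.02 and myeloma-supporting factors at −0.09. Nkain2 was again lower, at 28.9 against 156 CPM.

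The T-like classes differed little in their lists between the combination and lenalidomide. In CD8 T-like cells the exhaustion median was −0.07 (−0.14 to −0.02), and 0.10 with hashtags whose leading Trbv took over 20% left out, with Pdcd1 alone at least 1.5 times lower, at 50.6 CPM (47.5 to 53.8) against 88.4. The effector median was −0.18 (−0.24 to −0.13), with 2 of 16 members lower, the chemokines Ccl3 (156 against 294 CPM) and Ccl4 (678 against 1024). The memory list was at 0.11 (−0.02 without those hashtags) and the lenalidomide target list at 0.08. Nkain2 was at 37.5 CPM against 181. Cmss1 (1935 against 814), AY036118 (1033 against 445) and Cdk8 (1848 against 961) were above. Cmss1 was above in classical monocyte-like cells too (2406 against 906), and these genes lead an unnamed cluster of shallow barcodes (median 1338 UMIs) with 95 barcodes of the isotype control, 13 of the anti-CSF-1R, 150 of the lenalidomide and 247 of the combination library. Prg2 was at 61.6 against 153 CPM with 95% of the combination's UMIs in 1 barcode and a direction that turned with stricter cells (0.34). In CD4 T-like cells Cmss1 (1350 against 667), AY036118 (744 against 371) and the phosphatase gene Ptprj (59.5 against 29.8) were above as well. Tmem176b (88.5 against 288), Tmem176a (49.8 against 133) and Nkain2 (38.3 against 184) were below. The CD4 exhaustion and effector medians, both 0.16, changed sign at Leiden resolution 0.5 (−0.02 and −0.20). Genes of other cells differed in CD4 T-like cells, with MHC class II at −1.01, resident macrophage genes at −0.59 (C1qc, a complement gene of macrophages, at 21.6 against 63.0 CPM), the erythroid list at −1.43 and the neutrophil granule list at 0.93.

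The fourth comparison set the combination against the antibody alone, so lenalidomide and the genotype both change. Non-classical monocyte-like cells were at 0.89% against 5.6%, a log2 ratio of −2.65 (−3.11 to −2.23) that was −1.93 by markers after thinning. Their hashtag ranges overlapped, at 0.15% to 4.83% and 3.37% to 8.20%. Classical monocyte-like cells were at 50.0% against 50.1% as pooled shares. By hashtag the classical share ran from 18.3% to 71.7% in the combination and from 30.7% to 60.9% with the antibody, so the pooled values do not show equal shares. Regulatory T-like cells were at 9.09% against 6.34%, a log2 ratio of 0.52, and CD8 T-like cells at 40.7% against 49.6%. In CD8 T-like cells the exhaustion list was at 0.08 (0.03 to 0.14), turning to −0.03 without hashtags whose leading Trbv took over 20%, the effector list at −0.00 and the memory list at −0.01. The lenalidomide target list was at 0.21 with 0 of 9 members past 1.5 times. Ccr2 was at 126 CPM (121 to 131) against 77.7 (73.7 to 81.7) and Il31ra at 620 against 364. Like Cmss1 and AY036118, Il31ra is also among the leading genes of the unnamed cluster of shallow barcodes described above. Xcl1 was lower, at 183 CPM (178 to 189) against 360 (351 to 368), as were Cd7 (182 against 268) and Ccnb1ip1 (27.3 against 55.4), and Prg2 again rested on 1 barcode. In CD4 T-like cells Ifitm1 (122 against 48.2 CPM) and Ifitm2 (214 against 84.2) were higher, and Xcl1 (86.8 against 201), Spp1 (15.2 against 50.4) and Bcl3, a regulator of NF-kappa B (21.6 against 50.4), lower. Ccl3, at 103 against 50.0 CPM, turned with 1-hashtag barcodes only (−0.39) and at Leiden resolution 0.5 (−0.24). The effector list was at −0.32, exhaustion at −0.25, memory at 0.11 (−0.10 with centred genes) and the plasma cell and myeloma list at 0.81.

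In classical monocyte-like cells the combination lay above the antibody alone in the inflammatory list median and below it in both interferon list medians. Wfdc21 was at 241 CPM (235 to 248) against 52.4 (48.6 to 56.3), Lrg1, a secreted glycoprotein of inflammation, at 86.4 against 15 and Cxcl2 at 99.3 against 30.5. The inflammatory list was at 0.52 (0.43 to 0.58) with 2 of 8 members higher and at 0.24 with no minimum CPM, beside dissociation stress at 0.57 with 3 of 8. The type I interferon list was at −0.50 (−0.57 to −0.44), with 4 of 14 members lower. The interferon gamma list was at −0.48 with 3 of 11 members lower, including Gbp2 at 32.1 against 66.0, and Ifi205 (27.6 against 58.9) and Ifi213 (45.1 against 97.9) were lower. MHC class II was at 0.21, cell cycle at −0.14, neutrophil granule at 0.36 and myeloma-supporting factors at 0.16. Alternative activation was at 0.49, with Apoe at 331 CPM against 158, and −0.01 with no minimum CPM.

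Against the isotype control, the combination had an exhaustion median of −0.53 and an effector median of −0.40 in CD8 T-like cells, with 6 of 12 and 5 of 16 members lower. The reference is again the isotype control library. Leaving out its hashtags 2 and 3 drew the exhaustion medians of the other comparisons with it toward 0. In classical monocyte-like cells MHC class II was at 1.00, cell cycle at 0.72, the inflammatory list at 0.52, dissociation stress at 0.61 and type I interferon at −0.64. The neutrophil granule list was furthest from 0 there, at 2.42 (2.30 to 2.55), and at 0.42 with no minimum CPM. The design being 2 by 2, the fold of the combination against lenalidomide minus that of anti-CSF-1R against the isotype control gives the departure from additivity. For a list it is the difference of 2 medians, each over the members measured in its own comparison. The departure was −3.37 (−3.83 to −2.91) for the non-classical monocyte-like share, and −2.18 when cells were called by markers after thinning. The ratios behind −3.37 were −1.20 in WT mice and −4.57 in CRBN mice on lenalidomide. By hashtag the combination's share was 2.42%, 4.83%, 0.47%, 1.76% and 0.15%, beside a pooled 0.89%, so the size depends on how hashtags are weighted. Equal weights were not applied to shares. For the regulatory T-like share the departure was 0.51 (0.33 to 0.70), for the CD8 T-like share −0.13 and for the macrophage-like share −0.21 (−0.74 to 0.33). For the classical monocyte-like share it was 1.28, and 0.53 at Leiden resolution 0.5. In CD8 T-like cells it was 0.70 (0.58 to 0.77) for the exhaustion list, the antibody alone going with −0.77 and the antibody on top of lenalidomide with −0.07, and 0.20 for the effector list. Without isotype hashtags 2 and 3 these departures were 0.33 and 0.03, and without hashtags over 20% in every library 0.38 and 0.12. In classical monocyte-like cells it was −1.16 (−1.29 to −1.04) for MHC class II, −0.37 for type I interferon and 0.36 for the inflammatory list. The largest list departure was that of the neutrophil granule list, at −1.95 (−2.08 to −1.80), but −0.68 at Leiden resolution 0.5 and 0.07 with no minimum CPM. Combination against antibody and lenalidomide against isotype control, the other pair, had medians of 0.36 and 0.91 for this list. They were 0.21 and 1.60 for MHC class II and 0.08 and −0.40 for CD8 T-like exhaustion. Size and order of the list departures thus depend on the pair taken. With hashtags weighted equally the type I interferon departure turned to 0.18. These departures describe 4 libraries and were not tested.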

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

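The bound of 40% that sets mixed clusters apart was chosen after the data were seen, and no explanation was tested for the results in this part. The antibody went with opposite directions in classical monocyte-like cells in the 2 settings where it was added. The MHC class II list, the genes of antigen presentation to CD4 T cells, was at 0.67 (log2) for anti-CSF-1R against isotype control in WT mice and at −0.49 for the combination against lenalidomide in CRBN mice. The first of these was 0.03 at Leiden resolution 0.5 and 0.16 with hashtags weighted equally, so that value is near 0 there. At resolution 0.5 the class also took in 86.8% of the dendritic-like cells, so 0.03 describes a wider set of cells. The interferon gamma list was at 0.20 and −0.42 in the same comparisons. These differences were not tested, since each value compares 1 library with 1 library.

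Barcodes in clusters that mix cell types, which are in no class compared in the report and are used below only in the Nkain2 ranges, made up 18.88% of the anti-CSF-1R library, 17.17% of the lenalidomide library and 12.41% of the combination library, against 8.48% of the isotype control library. The largest such cluster, with T cell, monocyte and MHC class II genes together, held 119 barcodes of the isotype control, 1967 of the anti-CSF-1R, 1082 of the lenalidomide and 1888 of the combination library. The doublet caller had removed 15% of the isotype control barcodes beforehand and 3.39%, 1.46% and 2.98% of the others.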

How the results depend on the processing

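The settings with 1-hashtag barcodes, equal hashtags, isotype hashtags left out, hashtags with a leading Trbv over 20% left out of every library, a share of monocyte-like cells alone and a call by markers in thinned cells were added after the data were seen, as were the 5 lists whose moved values are all given here (CD8 T-like exhaustion and effector, and classical monocyte-like MHC class II, type I interferon and inflammatory). No paired analysis was possible because each group has 1 library. The surface protein values, their log-ratio and the protein gates were not run, as the feature tables listed hashtags only. Leiden resolution 0.5 gave no value for the dendritic-like and progenitor-like classes, as 86.8% of the former fell into the classical monocyte-like class and 98.0% of the latter into the neutrophil-like class, which alters the classical share and lists at that setting. A value counts as moved when it left the counting interval of the value reported, which depth makes narrow, and as changed in sign where that interval also excluded 0. Of 696 alternative values for genes 523 stayed within it, 163 moved and 10 changed sign, of 1120 for lists 783, 310 and 27, and of 174 for shares 143, 30 and 1. Except where a setting's construction shows it, the cause was not tested. The comparisons are abbreviated as antibody/isotype, lenalidomide/isotype, combination/lenalidomide, combination/antibody and combination/isotype, and all values are log2.

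The non-classical monocyte-like share kept its direction under all 7 settings tried, from −1.25 to −0.60 antibody/isotype and from −4.99 to −2.78 combination/lenalidomide, and was −4.04 there with genes centred per library. The call by markers gave the values nearest to 0, −0.60, 0.25 lenalidomide/isotype, −2.78 and −1.93 combination/antibody, and a departure of −2.18. The share was 1.22 lenalidomide/isotype as a share of classical and non-classical cells alone, a change of denominator. The CD8 T-like exhaustion list stayed between −0.95 and −0.28 antibody/isotype over 17 settings and the MHC class II list between 1.5 and 2.03 lenalidomide/isotype over 10. Leaving out isotype hashtags 1 to 5 in turn gave antibody/isotype exhaustion of −0.95, −0.66, −0.60, −0.89 and −0.86 and effector of −0.55, −0.25, −0.25, −0.46 and −0.43. The lenalidomide/isotype effector values were −0.42, −0.16, −0.14, −0.33 and −0.33, and exhaustion without hashtags 1 to 3 was −0.55, −0.30 and −0.31. Leaving out hashtags 2 and 3 together gave exhaustion of −0.40 and effector of −0.21 antibody/isotype, and −0.14 and 0.01 lenalidomide/isotype, where memory turned to −0.01. The departures were then 0.33 for CD8 exhaustion, 0.03 for CD8 effector and 0.00 for CD8 memory. With hashtags over 20% left out of every library exhaustion was −0.28 and effector −0.16 antibody/isotype, exhaustion turned to 0.10 and memory to −0.02 combination/lenalidomide with effector at −0.03, exhaustion turned to −0.03 combination/antibody with effector at −0.07, and the exhaustion departure was 0.38. The 20% was chosen with the shares in view, and the combination, whose highest was 19.4%, lost no hashtag.

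Stricter cells gave a classical share of 1.44 combination/lenalidomide and CD8 T-like exhaustion of −0.69 antibody/isotype and 0.01 combination/antibody. Their classical monocyte-like type I interferon was −0.07 antibody/isotype, −0.15 lenalidomide/isotype and −0.61 combination/antibody, MHC class II 1.74 lenalidomide/isotype and −0.60 combination/lenalidomide, and inflammatory 0.30 lenalidomide/isotype. Departures from additivity were −1.29 for MHC class II and −0.46 for type I interferon, and Prg2 in CD8 T-like cells turned to 0.34 combination/lenalidomide. With doublets kept the classical share was 1.48 combination/lenalidomide, type I interferon −0.12 antibody/isotype and −0.49 combination/lenalidomide, MHC class II 0.29 combination/antibody and Prg2 0.36 combination/lenalidomide.

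Leiden resolution 0.5 gave a classical share of −0.54 lenalidomide/isotype and 0.84 combination/lenalidomide, with a departure of 0.53. In CD4 T-like cells exhaustion turned to −0.02 and effector to −0.20 combination/lenalidomide. MHC class II in classical monocyte-like cells was 0.03 antibody/isotype, 1.99 lenalidomide/isotype, −1.17 combination/lenalidomide and 0.64 combination/antibody. Type I interferon there was 0.12 lenalidomide/isotype, −0.61 combination/lenalidomide and −0.33 combination/antibody, inflammatory 0.30 lenalidomide/isotype and 0.31 combination/antibody, resident macrophage 0.41 lenalidomide/isotype and interferon gamma 0.04 combination/isotype. Cd8a in CD4 T-like cells was −0.41 antibody/isotype, Ccl3 in CD4 T-like cells −0.24 combination/antibody, and Csf1r in classical monocyte-like cells −0.19 antibody/isotype and −0.07 combination/lenalidomide.

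Centring genes per library gave a classical share of 0.38 antibody/isotype, −1.14 lenalidomide/isotype and 0.09 combination/antibody, and CD4 T-like memory of −0.10 combination/antibody. MHC class II in classical monocyte-like cells was 0.56 antibody/isotype and 0.36 combination/antibody, and type I interferon −0.05 antibody/isotype, −0.09 lenalidomide/isotype, −0.61 combination/lenalidomide and −0.67 combination/antibody. The departures were −0.95 for MHC class II and −0.56 for type I interferon, and Csf1r was −0.35 antibody/isotype.

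TMM scaling gave CD8 T-like exhaustion of −0.34 and effector of −0.23 lenalidomide/isotype. The mean over cells gave exhaustion of 0.16 and effector of 0.09 combination/antibody, MHC class II of 0.54 and type I interferon of −0.12 antibody/isotype, departures of 0.28 for CD8 effector and −0.46 for type I interferon, and Ccl5 in macrophage-like cells of −0.00 antibody/isotype. A pseudocount of 1 CPM gave exhaustion of −0.88 antibody/isotype and −0.47 lenalidomide/isotype, effector of −0.44 antibody/isotype, MHC class II of 0.89 antibody/isotype and 1.76 lenalidomide/isotype, inflammatory of 0.67 combination/lenalidomide and 0.58 combination/antibody, type I interferon of −0.61 combination/antibody and departures of 0.77 for exhaustion and −1.46 for MHC class II.

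No minimum CPM, which lets in members with few UMIs, gave classical monocyte-like MHC class II of 0.51 antibody/isotype and inflammatory of −0.01 antibody/isotype, 0.08 combination/lenalidomide and 0.24 combination/antibody. Resident macrophage was 0.03 antibody/isotype, 0.01 lenalidomide/isotype and 0.01 combination/isotype, alternative activation −0.01 lenalidomide/isotype and −0.01 combination/antibody, and type I interferon −0.46 combination/lenalidomide. The departures were −1.0 for MHC class II, −0.24 for type I interferon, 0.09 for inflammatory and 0.07 for neutrophil granule. Thinning to 1000 UMIs turned the share of classical monocyte-like cells with a Cd74 UMI to 0.11 antibody/isotype.

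Use of 1-hashtag barcodes gave a regulatory T-like share of 0.66 and a classical share of 0.08 combination/antibody and a CD8 T-like share of −0.10 lenalidomide/isotype. CD8 T-like exhaustion was −0.69 antibody/isotype, −0.33 lenalidomide/isotype and 0.16 combination/antibody, CD8 T-like effector 0.07 combination/antibody and CD4 T-like effector −0.04 combination/lenalidomide. MHC class II was 0.37 antibody/isotype and 0.40 combination/antibody and type I interferon −0.10 antibody/isotype. The departures were 0.28 for CD8 effector, −0.86 for MHC class II, −0.47 for type I interferon and 0.71 for the regulatory T-like share. Cd8a in CD4 T-like cells was −0.47 and Malat1 in macrophage-like cells −0.03 antibody/isotype, Prg2 in CD8 T-like cells 1.35 and Csf1r in classical monocyte-like cells 0.25 combination/lenalidomide, and Ccl3 in CD4 T-like cells −0.39 combination/antibody.

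Equal hashtags gave CD8 T-like effector of −0.28 antibody/isotype, −0.19 lenalidomide/isotype and −0.09 combination/lenalidomide and exhaustion of 0.25 combination/antibody. In CD4 T-like cells effector was −0.12 combination/lenalidomide, memory −0.03 combination/antibody and lenalidomide target −0.01 combination/antibody. The classical monocyte-like MHC class II list was 0.16 antibody/isotype, 2.03 lenalidomide/isotype, −0.72 combination/lenalidomide and 0.69 combination/antibody, and type I interferon −0.31, −0.48, −0.13 and −0.39 in the same order. Inflammatory was 0.43 antibody/isotype, 0.99 combination/lenalidomide and 0.59 combination/antibody, dissociation stress −0.02 lenalidomide/isotype and resident macrophage 0.29 lenalidomide/isotype. The departures were −0.87 for MHC class II, 0.18 for type I interferon, 0.57 for inflammatory and 0.00 for CD8 memory.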

Other observations

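Of the tests in this part, the test on Csf1r-expressing cells and the test on library batches for Nkain2, the depth test and the whole-cause test on hashtags 2 and 3 for exhaustion, the several-cell test for the non-classical share with the antibody alone, and both tests for the combination against lenalidomide were chosen after the result was seen. Non-classical monocyte-like cells differed in content as well as in share. Their MHC class II list was at 1.15 with anti-CSF-1R and at 1.58 with lenalidomide, each against the isotype control, with 5 and 6 of 7 members at least 1.5 times higher and 0 lower. Cd74 in them stood at 1918 CPM in the isotype control, 4270 with anti-CSF-1R, 5768 with lenalidomide and 6603 with the combination, and H2-Aa at 169, 623, 835 and 994. Apoe, a lipid carrier, was at 3920, 1568, 2680 and 2653 CPM. Dendritic-like cells, a cluster with monocyte genes as well (a Ccr2 UMI in 88.3% of its cells and a Flt3 UMI in 11.5%), had MHC class II lists of 0.20 with anti-CSF-1R and 0.74 with lenalidomide, with H2-Aa at 3180, 3648, 5722 and 5000 CPM in the 4 libraries.

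Regulatory T-like cells of the anti-CSF-1R library had a T effector list of 0.41 against the isotype control, with 4 of 15 members higher and 1 lower. Gzma went the other way, at 61.2 CPM in the isotype control, 37.2 with anti-CSF-1R, 45.5 with lenalidomide and 18 with the combination, and Il10, an inhibitory cytokine, was at 23, 10.8, 40.5 and 24.2. Genes of macrophages differed in the same class. Its resident macrophage list was at −1.01 for the combination against lenalidomide, with 9 of 11 members lower, and the complement gene C1qc stood at 121, 89.8, 102 and 37.8 CPM in the 4 libraries. In CD4 T-like cells C1qc was at 73.0, 47.9, 63.0 and 21.6 CPM.

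The first pattern weighed is Nkain2, which was lower in both libraries with the antibody, with log2 folds from −3.19 to −2.47 for anti-CSF-1R against the isotype control and from −2.27 to −1.74 for the combination against lenalidomide, over the classes with at least 100 cells in every library, mixed and unnamed ones included. A response limited to cells that express Csf1r is argued against by CD8 T-like cells, where Csf1r is near 0 and the Nkain2 fold was −2.82. Free RNA is argued against by depth, since in isotype CD8 T-like cells the CPM in the shallowest cells over that in the deepest was 1.01 for Nkain2 against 4.86 for S100a8. A difference between library batches and an effect of the antibody on all cells cannot be told apart, because each library is its own batch and the anti-CSF-1R folds spanned only 0.72 over those classes.

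The second pattern is the higher exhaustion genes in CD8 T-like cells of the isotype control. A difference in depth is argued against by thinning, after which the share with a Pdcd1 UMI was still 2.43 times that with anti-CSF-1R, and barcodes with several cells by the value of −0.69 with 1-hashtag barcodes. An expanded T-cell clone in a single hashtag may contribute, since in hashtag 3 cells with Trbv19 had an exhaustion median 1.95 above that of other cells, with Pdcd1 at 470 and 67.4 CPM. A shared segment does not by itself show a clone. Such a gap was not particular to the isotype control, being 1.87 in hashtag 4 with lenalidomide (Pdcd1 at 429 and 22.6 CPM) but −1.50 in hashtag 1 there. Whether such clones are the whole cause cannot be told apart from the antibody, as leaving out hashtags 2 and 3 gave −0.40 and leaving out such hashtags in every library −0.28. Neither value can decide this, since barcodes with several hashtags or none, which can hold cells of those hashtags, stayed in. An effect of the antibody stays open and untested, since there is 1 library per group.

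The third pattern is the lower non-classical monocyte-like share with the antibody. Barcodes with several cells are argued against, as 1-hashtag barcodes gave −1.09 for the antibody alone and −4.23 for the combination against lenalidomide. Where the cluster boundary falls is argued against as the whole cause for the combination, where a call from markers in thinned cells gave −2.78. The cluster call gave −4.57 there, so the size depends on how the cells are called. For the antibody alone the boundary is not argued against, as the marker call gave −0.60, too close to its bound to decide. An effect of the antibody on these cells is a hypothesis consistent with those values, and the CD64 sort, the hidden binding of sorting antibodies and, across the 2 settings, the genotype and lenalidomide were not tested.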
